A study of Drosophila melanogaster with 6 samples.

How the data were processed

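Polyadenylated or total RNA selection is not given in the sources used here; per the labels' protocols, RNA was extracted with Trizol straight after dissection of larval fat bodies, and libraries were made with an Illumina TruSeq RNA kit, in 3 control and 3 AKH overexpression samples. Each library is named by its group and the replicate number in its title.

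The authors deposited a table of raw read counts per gene and a table of RPKM, reads scaled by gene length and library total. Per the submitters' processing notes, Bowtie2 2.0.6, TopHat2 2.0.9, HTSeq 0.5.4p3 and DESeq 1.10.1 were used with genome build BDGP5; the role of each tool, the annotation release, the treatment of strand and of reads matching several genes, and any filters are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be shared between them. The deposited counts are whole numbers for 15796 genes, of which 115 have identifiers outside FlyBase and 15681 have FlyBase identifiers. Symbols from the reference name table were found for 15001 of these, and the other 680 keep their identifier. The deposited RPKM values are the deposited counts divided by the library total and by 1 gene length per gene, which was checked in 7684 genes of more than 50 counts in each library (largest relative spread of the implied length 1.04e-07). The tables share 15795 genes. The reference annotation at hand is of a later build than the authors', so no coordinates are given and gene order from it was used only to find neighbours.

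Library totals were 29803513 to 33150911 counts, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0905 to 0.101 CPM per library. Intervals and limits based on counts cover counting error only. The chi-square statistic of counts per degree of freedom was 38.4 to 92.5 between libraries of a group, so no library repeats another within sampling noise. Pearson correlations of log2 CPM were 0.945 to 0.982 within and 0.908 to 0.961 between groups.

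Counts were tested with edgeR 4.0.16 in R 4.3.3, with the default expression filter, TMM scaling and quasi-likelihood F tests of the group term, with no covariate, on all 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 10705 tested genes were called. The square root of the common dispersion was 0.308. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists for pathways, gene families and markers of tissues a dissection could carry were fixed before the data were examined. Of their 1148 names 1086 were found in the count table. The 38 lists with at least 5 tested genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. For each list, p-values were also adjusted over the list alone.

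The genes named in the text follow a rule also fixed before the data were examined. It takes Akh, AkhR and w, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups, and for each list up to 3 called members with the smallest p, or its most abundant member if none was called. The rule gave 78 genes, 70 of them called. Genes named outside it identify the members behind a count of 5 or fewer or are in the closing section. They were chosen after their values were seen. Before the closing section these are Pgd, sug, tobi, PhKgamma, SdhB, CG3999, Cyp4p1, Cyp4ad1, sut2, CG4607, Ncc69 and the protease gene Jon65Aiv.

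Alternatives covered scaling (RLE, upper quartile, library size, TMM without the 20 most abundant genes), tools (DESeq2 1.42.0, limma-voom, edgeR with robust estimation), filters, thresholds, limma on log2(RPKM + 1) and log2(RPKM + 0.1), the replicate number as a block, and leaving out each library. After the data were seen, fits without a pair of libraries were added. On simulated counts with 200 changed genes, made for AKH overexpression against control with 10416 genes tested, edgeR recovered 53% of changes of 1 and 79% of changes of 2 on the log2 scale, and 2.94% of its calls were unchanged genes. DESeq2, with 10691 genes tested, recovered 66% and 85%, with 23.0% of calls unchanged genes. Figures were drawn with matplotlib 3.10.9.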

Results

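RNA was measured in the fat body, the storage and secretory organ of the fly, dissected from late 3rd instar Drosophila melanogaster larvae. The 3 control libraries came from larvae with the fat body driver R4-Gal4 alone, and the 3 AKH overexpression libraries from larvae that also carried UAS-AKH, which places the adipokinetic hormone gene under that driver. The libraries held 29803513 to 33150911 counts each, and the 20 most abundant genes took 46.1% to 51.7% of them. A total of 10705 genes had enough counts to be tested. Values are CPM, counts scaled to a common library size, with the SD over n = 3 libraries, and log2 fold changes are AKH overexpression against control with their standard errors (SE). Gene p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, and a gene is said to have risen or fallen only when this adjusted p was under 0.05. The labels do not say whether the libraries of a group came from separate pools of larvae, so the p-values measure the spread between these libraries, which may be technical in part.

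The comparison asks how forced production of the hormone in the fat body changes that organ's own transcripts. Akh (FBgn0004552), which encodes a glucagon-like peptide normally made by the corpora cardiaca, rose from 2.18 ± 0.319 CPM to 1854 ± 227 CPM. AkhR (FBgn0025595), the receptor through which the fat body senses the hormone, fell from 142 ± 26.8 to 39.8 ± 2.25 CPM. The lipid droplet coat protein Lsd-1 (perilipin) also fell, as did the lipase bmm (brummer), whose call was lost without any 1 AKH replicate. In the fatty acid beta-oxidation list 6 of 30 genes fell, and in the citric acid cycle list 4 of 15. The gene set test camera called both lists with a preset correlation but not with an estimated one (adjusted p = 0.935 and 0.815). The aminotransferases Got1 and Got2, the pentose phosphate enzyme Zw and the glycogen branching enzyme AGBE rose.

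**Figure D1:**
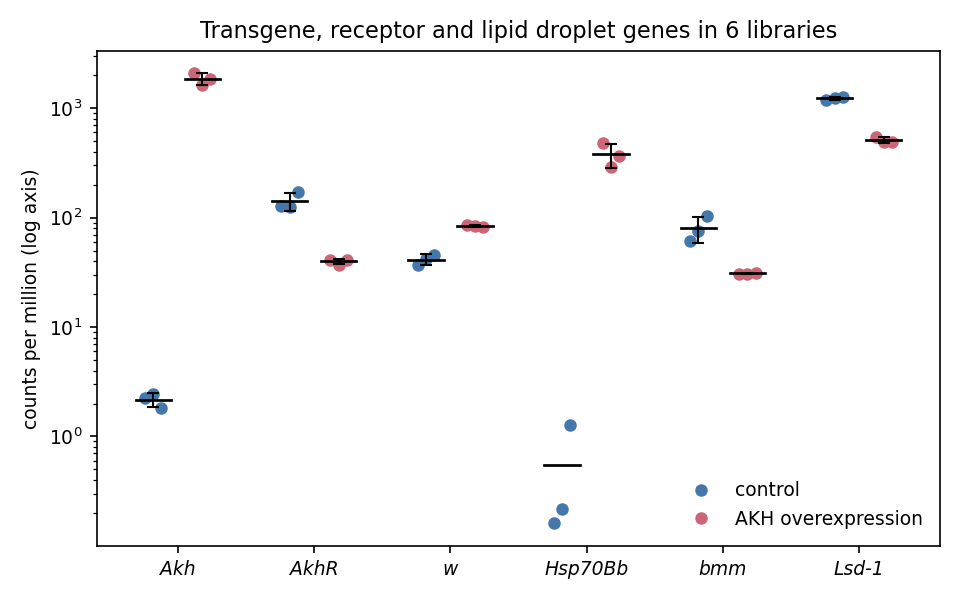
CPM of 6 genes on a log axis in the 3 control and 3 AKH overexpression libraries. Points are libraries, horizontal lines are group means and vertical bars are the SD (not drawn for Hsp70Bb in controls, where it reaches below 0). Akh lies at 2.18 CPM on average in controls and at 1854 CPM with the transgene, and AkhR at 142 and 39.8 CPM.

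The log2 fold change of Akh was 9.73 (SE 0.21, adjusted p = 3.5e-05). An exact two-sided permutation test on its log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. AkhR changed by -1.84 (SE 0.15, adjusted p = 0.0024). The white gene w (FBgn0003996), whose small version is the usual marker on fly transgenes, rose by 1.01 (SE 0.10), from 41.4 ± 4.65 to 83.4 ± 1.497 CPM. Of 26 tested genes of the hormone's pathway and its second messengers, 2 rose (Akh and Pka-R1), 1 fell (AkhR) and 23 were not called. The counts were 2 and 1 when adjusted over the list alone, and camera, the gene set test of limma, gave adjusted p = 0.697. Of 5 tested genotype markers, 3 rose (Akh, w and ry), or 4 when adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.514 with an estimated correlation). Since this list holds the overexpressed gene itself, its call was largely set by the genotype. The calls of Akh, AkhR and w held when any 1 library was left out. That of Pka-R1 (log2 fold change 0.73) was lost without control replicate 1 or 2 or AKH replicate 1 or 3, with adjusted p up to 0.136, and that of ry (0.48) in 5 of the 6 such fits, all except that without control replicate 3, with adjusted p up to 0.195.

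In all, 404 genes changed, 200 of them higher and 204 lower with AKH overexpression, so 49.5% had risen; the share was 39.2% to 61.2% when 1 library was left out and 40.1% with DESeq2. At least a 2-fold change was seen in 119 of the risen and 128 of the fallen genes. The groups did not overlap in 2601 genes, 24.3% of those tested, where chance gives 10% as a mean over all splits into 3 and 3. Genes vary together, so a single split can lie far from that mean. The shares of the other splits were not computed, and this excess alone does not show a group effect. The number of changed genes fell to 144 without AKH replicate 1, to 182 without AKH replicate 3, to 189 without control replicate 1 and to 261 without AKH replicate 2. DESeq2 called 986 genes. The camera tests described here called 11 of 38 gene lists with a preset correlation of 0.01. With an estimated correlation they called 0, where 2 had an unadjusted p under 0.05. The rotation test fry called 1, the genotype markers, which hold Akh itself and are also among the 11.

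**Figure D2:**
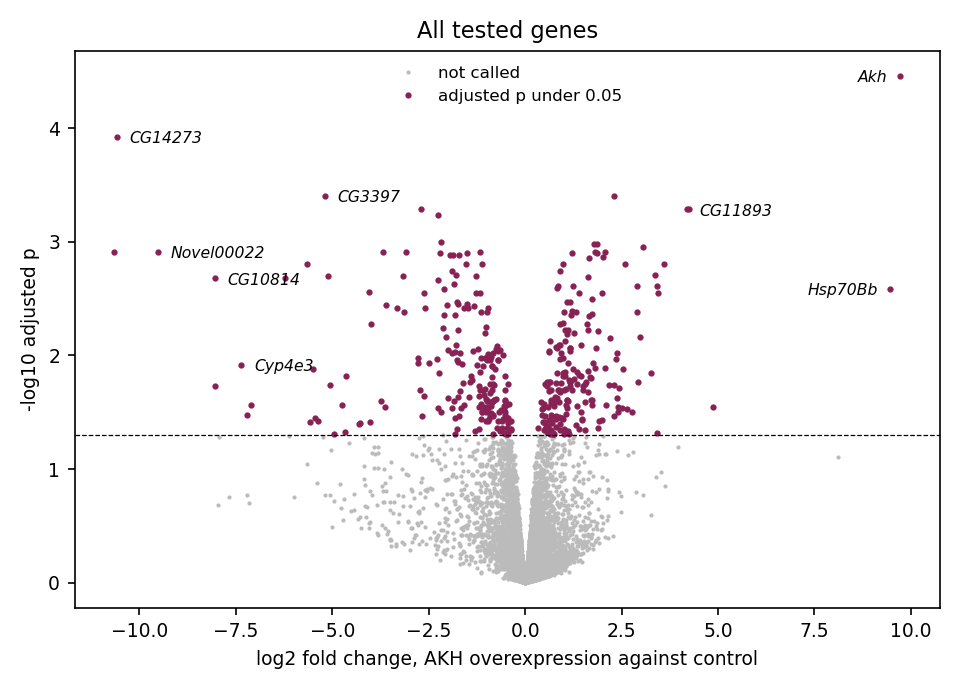
Log2 fold change of each of the 10705 tested genes against the -log10 of its adjusted p, with the 404 called genes in dark red and the dashed line at an adjusted p of 0.05. Akh at 9.73 and Hsp70Bb at 9.47 lie far to the right, and CG14273 at -10.58 far to the left.

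Besides Akh, the largest increases among genes of at least 5 CPM were in Hsp70Bb, meep, CG11893, Sodh1, LysP, CG9119, CG6293, CG13659 and Miox. Miox, myo-inositol oxygenase, rose from 310 ± 83.7 to 2320 ± 351 CPM (log2 fold change 2.90, SE 0.23, adjusted p = 0.0024). Sodh1, a sorbitol dehydrogenase, rose from 30.9 ± 9.48 to 377 ± 43.5 CPM, and LysP, a lysozyme, from 4.94 ± 2.01 to 53.4 ± 3.28 CPM. The log2 fold changes of meep and CG11893 were 4.25 (SE 0.19) and 4.19 (SE 0.18). Hsp70Bb rose from 0.552 ± 0.629 to 380 ± 94.4 CPM (log2 fold change 9.47, SE 0.78, adjusted p = 0.0026). It has near-identical copies whose reads the counting could split, and the 5 other listed Hsp70 copies together held 93 counts in the controls and 26 with AKH overexpression.

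Among genes of at least 5 CPM, the 10 largest decreases were in CG14273, Novel00022 (an identifier outside FlyBase), CG10814, Cyp4e3, Cyp304a1, Srr, CG3397, CG8654, CG8788 and TotC. CG14273 had 3477 counts over the 3 controls and 2 over the 3 AKH overexpression libraries, a ratio of 1815 with a 95% counting interval of 502 to 14995. Novel00022 had 950 and 1, a ratio of 992 (178 to 39219). Srr, a serine racemase, fell from 226 ± 80.7 to 4.48 ± 1.196 CPM, CG3397 from 273 ± 35.3 to 7.47 ± 1.61 CPM, and TotC, a stress-induced secreted peptide of the Turandot family, from 11.9 ± 2.51 to 0.910 ± 0.195 CPM. Among these risen and fallen genes only the call of Cyp4e3 was lost on leaving out a library, without AKH replicate 1, 2 or 3 (adjusted p up to 0.0608). Under limma-voom the calls of Novel00022, Cyp4e3 and Cyp304a1 were lost.

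Among lipolysis and lipid droplet genes Lsd-1 fell from 1232 ± 45.4 to 510 ± 33.7 CPM (log2 fold change -1.27, SE 0.10, adjusted p = 0.0020) and bmm from 79.7 ± 21.3 to 30.9 ± 0.351 CPM (-1.37, SE 0.19, adjusted p = 0.016). They were the 2 called of 13 tested, with 11 not called. The list had 1 risen and 2 fallen genes when adjusted over the list alone (camera adjusted p = 0.620). In the fatty acid beta-oxidation list, 6 of 30 genes fell, 0 rose and 24 were not called, and 1 had risen and 10 fallen when adjusted over the list alone. The thiolase yip2 fell by 1.78 (SE 0.16) on the log2 scale, from 560 ± 99.6 to 164 ± 16.0 CPM. The medium-chain acyl-CoA dehydrogenase Mcad fell by 1.35 (SE 0.16), from 1010 ± 206 to 396 ± 12.1 CPM. The list member CG10814, also among the 10 largest decreases above, fell from 191 ± 87.5 to 0.716 ± 0.506 CPM. The list's camera adjusted p was 2.9e-05, and the adjusted p = 0.935 with an estimated correlation. Its median was -0.30 on the log2 scale, and the muscle, midgut and cuticle marker lists, which camera also called lower with the preset but not with an estimated correlation (adjusted p = 0.650, 0.650 and 0.815), had medians of -0.58, -3.34 and -0.37. The call of bmm was lost without AKH replicate 1, 2 or 3 (adjusted p up to 0.0885) and that of Mcad without AKH replicate 1 or 3 (up to 0.0556).

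Of 20 tested genes of fatty acid and triglyceride synthesis, 2 rose, 3 fell and 15 were not called, with 5 risen and 6 fallen when adjusted over the list alone (camera adjusted p = 0.948). Zw, the glucose-6-phosphate dehydrogenase that makes NADPH, rose by 1.59 (SE 0.16), from 37.7 ± 7.81 to 113 ± 6.05 CPM. Men, the malic enzyme, which also makes NADPH, fell by 2.77 (SE 0.34) on the log2 scale, from 817 ± 242 to 120 ± 39.8 CPM, and Lpin, the phosphatidate phosphatase lipin, by 1.00 (SE 0.17). The other 2 called genes were Pgd (0.75), the next enzyme of the pentose phosphate pathway after the lactonase, and the transcription factor gene sug (-1.31). The call of Zw held when any 1 library was left out. That of Men was lost without AKH replicate 3 (adjusted p = 0.0524), and those of Lpin, Pgd and sug were lost in 5, 5 and 4 of the 6 such fits, with adjusted p up to 0.152, 0.173 and 0.177.

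**Figure D3:**
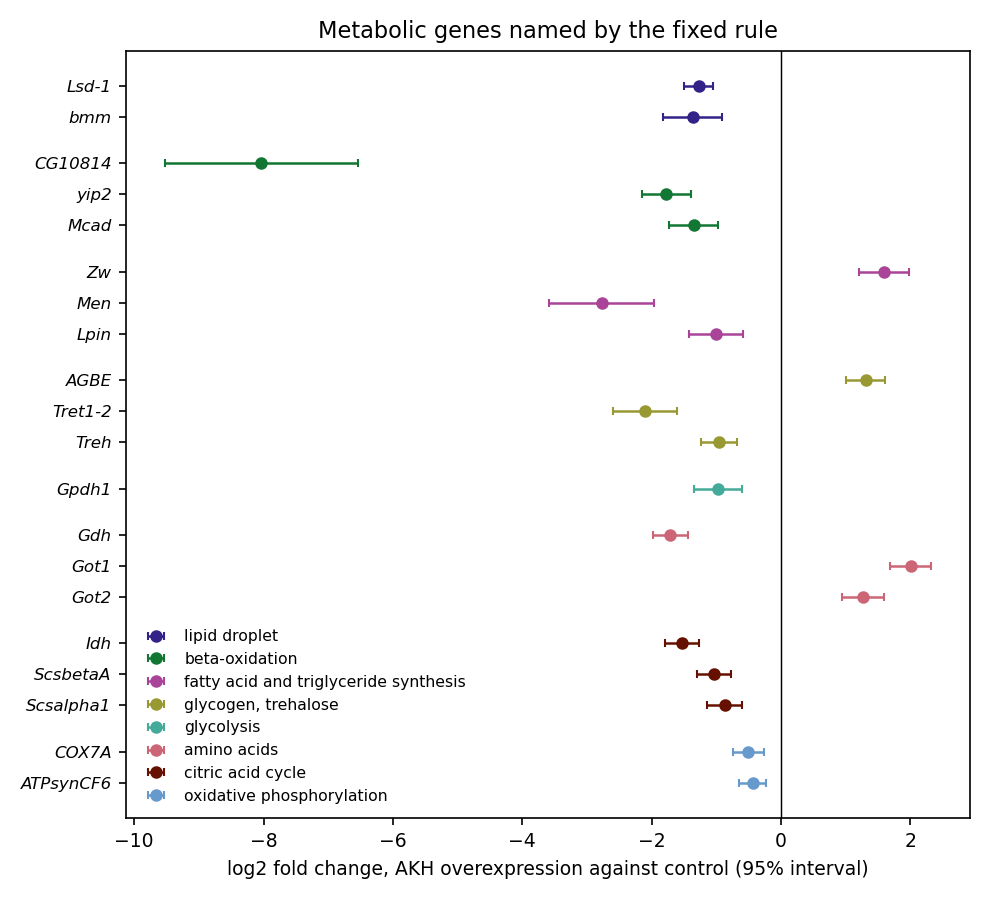
Log2 fold change, AKH overexpression against control, of metabolic genes picked by the rule set in advance, coloured by gene list, with 95% intervals from the fit to 3 against 3 libraries. Zw, AGBE, Got1 and Got2 lie above 0 and the other genes drawn lie below it, CG10814 farthest at -8.04.

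Carbohydrate and amino acid enzymes moved in both directions. AGBE rose by 1.31 (SE 0.12), from 89.8 ± 13.4 to 223 ± 12.8 CPM, whereas Treh, trehalase, fell by 0.96 (SE 0.11) on the log2 scale. Tret1-2, a gene of the trehalose transporter family, fell by 2.10 (SE 0.20) at low abundance, from 3.69 ± 0.548 to 0.859 ± 0.0768 CPM. The glycogen and trehalose list had 3 risen, 2 fallen and 10 uncalled genes of 15 tested, and 4 risen and 3 fallen when adjusted over the list alone (camera adjusted p = 0.590). Its other risen genes were tobi (2.37), an alpha-glucosidase gene, and PhKgamma (0.45). In glycolysis 1 of 18 genes changed, Gpdh1, glycerol-3-phosphate dehydrogenase, which fell by 0.98 (SE 0.15) on the log2 scale. DESeq2 called 7 glycolysis genes, 5 of them higher, and limma-voom 1. When adjusted over the list alone, 6 had risen and 2 fallen (camera adjusted p = 0.348).

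Of 27 genes of gluconeogenesis and amino acid catabolism, 3 rose, 6 fell and 18 were not called, with 4 and 9 when adjusted over the list alone (camera adjusted p = 0.530). The cytosolic and mitochondrial aspartate aminotransferases rose, Got1 from 83.5 ± 12.05 to 335 ± 27.3 CPM (log2 fold change 2.01, SE 0.13, adjusted p = 0.0014) and Got2 from 406 ± 60.8 to 984 ± 45.7 CPM (1.28, SE 0.13). The other risen gene was CG3999 (1.03). Glutamate dehydrogenase, Gdh, fell from 622 ± 72.1 to 190 ± 4.48 CPM (-1.71, SE 0.11, adjusted p = 0.0013). The calls of AGBE, Tret1-2, Got1, Got2, CG3999 and Gdh held when any 1 library was left out. Those of Treh and tobi were each lost in 1 such fit, Treh without AKH replicate 1 (adjusted p = 0.0607) and tobi without control replicate 1 (0.0504), Gpdh1 in 4 (without control replicate 1 or 3 or AKH replicate 1 or 3, up to 0.112), and PhKgamma in 5 (all except without control replicate 3, up to 0.201).

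In the citric acid cycle list 4 of 15 genes fell, 0 rose and 11 were not called, with 1 risen and 7 fallen when adjusted over the list alone. Idh, the NADP-dependent isocitrate dehydrogenase, fell from 824 ± 42.8 to 286 ± 27.2 CPM (log2 fold change -1.53, SE 0.11, adjusted p = 0.0016), and the succinyl-CoA synthetase subunits ScsbetaA and Scsalpha1 by 1.03 (SE 0.11) and 0.87 (SE 0.11) on the log2 scale. SdhB (-0.36) was the other called gene. The camera adjusted p was 0.0019, and the adjusted p = 0.815 with an estimated correlation. All 44 tested oxidative phosphorylation genes had a negative log2 fold change, with a median of -0.32; the muscle and midgut marker lists also had negative medians, -0.58 and -3.34. Of these 44 genes 2 fell over all genes, COX7A (-0.50, SE 0.10) and ATPsynCF6 (-0.44, SE 0.09), 42 were not called, and 37 had fallen when adjusted over the list alone; DESeq2 called 24 and limma-voom 1. The list's camera adjusted p was 6.6e-16, and the adjusted p = 0.815 with an estimated correlation. Calls lost when 1 library was left out were those of Scsalpha1 (without any 1 AKH replicate), COX7A and SdhB (in all 6 fits), and ATPsynCF6 (in all except without control replicate 2), with adjusted p up to 0.0667, 0.201, 0.210 and 0.205.

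Cytosolic ribosomal protein genes had a median log2 fold change of -0.32, beside medians of -0.58, -3.34 and -0.37 in the muscle, midgut and cuticle marker lists. Of 86 tested, 3 fell (RpL22, sta and RpS20, by 0.53, 0.56 and 0.54), 0 rose and 83 were not called, and 50 had fallen when adjusted over the list alone; DESeq2 called 46 and limma-voom 4. The camera adjusted p was 6.7e-19, and the adjusted p = 0.815 with an estimated correlation. The list's mean log2 CPM was 8.82, 8.81 and 9.01 in control replicates 1 to 3. In AKH replicates 1 to 3 it was 8.74, 8.59 and 8.58, where midgut markers were at -0.848, 2.00 and -0.453. Whether loss of muscle, midgut or cuticle RNA lowered this list, or any other list set beside those medians, was not tested. Of 33 ribosome biogenesis genes edgeR called 0, also 0 when adjusted over the list alone, with 5 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Their median was -0.14 (camera adjusted p = 0.00083; adjusted p = 0.970 with an estimated correlation), and the most abundant, Non1, was at 252 ± 20.7 and 189 ± 12.4 CPM. The camera call of this list was lost without control replicate 1 (adjusted p = 0.101). The calls of RpL22, sta and RpS20 were lost in 5, 5 and 6 of the fits without 1 library, with adjusted p up to 0.153, 0.201 and 0.205.

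Among fat body secreted factors and lipoproteins 2 of 23 genes fell, the iron carrier transferrin Tsf1 (762 ± 67.7 to 332 ± 78.5 CPM) and the activin ligand daw (146 ± 16.6 to 81.2 ± 16.2 CPM), 0 rose and 21 were not called, with 0 risen and 3 fallen when adjusted over the list alone. The camera adjusted p was 0.0127, and the adjusted p = 0.815 with an estimated correlation; without control replicate 3 it was 0.0875. The list's median was -0.28, beside the -0.58, -3.34 and -0.37 of the muscle, midgut and cuticle marker lists. Of 21 insulin and FOXO signalling genes 1 fell, melt (-0.76, SE 0.09), which encodes an adaptor of that pathway, also 1 when adjusted over the list alone (camera adjusted p = 0.279). The 8 larval serum and storage protein genes had 0 calls by edgeR, DESeq2 and limma-voom, 0 when adjusted over the list alone and 0 with an unadjusted p under 0.05. The most abundant, Lsp1gamma, was at 90857 ± 15555 CPM in controls and 113021 ± 5191 CPM with AKH overexpression, a difference within the spread between libraries (adjusted p = 0.47; camera for the list 0.636). The calls of Tsf1 and daw were lost in 4 and 5 of the 6 fits without 1 library (adjusted p up to 0.113 and 0.150), and that of melt in 0.

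Of 18 ecdysone response genes edgeR called 0, also 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom (camera adjusted p = 0.951). The most abundant, Cth, was at 367 ± 49.5 and 438 ± 43.1 CPM. The list's mean log2 CPM differed within groups, at 4.68, 5.46 and 3.71 in control replicates 1 to 3. In AKH replicates 1 to 3 it was 4.30, 4.62 and 3.78. The lack of calls therefore does not show that the libraries were matched in stage. Of 29 autophagy and lysosome genes edgeR called 0, also 0 when adjusted over the list alone, with 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.636), and Atg8a was at 232 ± 30.1 and 274 ± 8.67 CPM. In the humoral immunity list 2 of 35 genes rose, the serpin gene nec (1.08) and the recognition protein gene PGRP-SD (1.70), and 1 fell, TotC, with 4 and 8 when adjusted over the list alone (camera adjusted p = 0.530). The stress and detoxification list had 2 risen genes of 38, GstD10 and GstO2, and 3 risen and 1 fallen when adjusted over the list alone (camera adjusted p = 0.620). In the endoplasmic reticulum stress list Herp (0.82) alone of 21 genes rose, also 1 when adjusted over the list alone (camera adjusted p = 0.957), and in the heat shock list Hsp70Bb alone of 14, also 1 (camera adjusted p = 0.176). Calls lost when 1 library was left out were those of PGRP-SD (in 4 of the 6 fits), GstD10 (4), GstO2 (6) and Herp (5), with adjusted p up to 0.0734, 0.119, 0.121 and 0.0933.

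Of 67 cytochrome P450 genes 7 rose and 4 fell, with 11 and 6 when adjusted over the list alone (camera adjusted p = 0.620). Cyp304a1 fell from 36.4 ± 14.9 to 0.485 ± 0.201 CPM, and Cyp4p2 rose from 17.6 ± 1.61 to 41.8 ± 3.34 CPM. The other fallen genes were Cyp4e3, Cyp4p1 (-1.01) and Cyp4ad1 (-0.82). Glutathione transferases had 3 risen of 32 (GstD10, GstE13 and GstO2), 4 when adjusted over the list alone (camera adjusted p = 0.138), and UDP-glycosyltransferases 1 of 23 (Ugt35C1, 1.56), 2 when adjusted over the list alone (camera adjusted p = 0.957). In the amino acid and sugar transporter list, which is broader than its name, 3 of 25 genes rose and 3 fell, with 4 and 3 when adjusted over the list alone (camera adjusted p = 0.697). The sugar transporter gene sut1 rose from 154 ± 29.5 to 509 ± 55.7 CPM, and the amino acid transporter genes mnd and gb fell by 0.71 (SE 0.08) and 0.77 (SE 0.10) on the log2 scale. The other called genes of this list were sut2 (1.16), CG4607 (0.88) and Ncc69 (-0.56), of which Ncc69 is not counted here as an amino acid or sugar transporter. In the cell cycle list 1 of 29 genes rose, fzr (0.40), an activator of the anaphase-promoting complex, also 1 when adjusted over the list alone (camera adjusted p = 0.778). The calls of Cyp304a1, Cyp4p2 and sut1 held when any 1 library was left out, and those of GstE13, Ugt35C1, fzr, mnd and gb were lost in 5, 5, 6, 2 (without control replicate 1 or AKH replicate 1) and 1 (without AKH replicate 3) of the 6 fits, with adjusted p up to 0.140, 0.135, 0.121, 0.0574 and 0.0538. Those of sut2, CG4607, Ncc69, Cyp4p1 and Cyp4ad1 were lost in 5, 5, 4, 4 and 5 of them, with adjusted p up to 0.0990, 0.132, 0.144, 0.103 and 0.141.

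Transcripts of neighbouring tissues differed between libraries. The midgut protease gene Jon65Aiv was at 1770, 2495 and 904 CPM in control replicates 1 to 3 and at 1.89, 464.5 and 0.522 CPM in AKH replicates 1 to 3, without passing the test (log2 fold change -3.47, adjusted p = 0.472). Of 15 midgut markers 1 fell, the mannosidase gene LManV (4.35 ± 2.37 to 0.0912 ± 0.133 CPM), 0 rose and 14 were not called, with 2 fallen when adjusted over the list alone and a median of -3.34 (camera adjusted p = 0.000212; adjusted p = 0.650 with an estimated correlation). Of 18 muscle markers the myosin light chain genes Mlc2 (-0.83) and Mlc1 (-0.96) fell, 7 when adjusted over the list alone, with a median of -0.58 (camera adjusted p = 2.3e-06; adjusted p = 0.650 with an estimated correlation). Of 34 cuticle and epidermis markers 1 fell, Twdlbeta (-2.01), with 1 risen and 3 fallen when adjusted over the list alone (camera adjusted p = 0.00427; adjusted p = 0.815 with an estimated correlation). Of 15 nervous system markers 1 rose, the calcium channel gene cac (4.78 ± 1.47 to 35.8 ± 8.66 CPM), also 1 when adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.970 with an estimated correlation). The call of cac held when any 1 library was left out, and those of LManV, Mlc2, Mlc1 and Twdlbeta were lost in 4, 3, 6 and 5 of the 6 fits (adjusted p up to 0.147, 0.0730, 0.147 and 0.111). The camera call of the cuticle list was lost without AKH replicate 2 (adjusted p = 0.0880) and among genes with a mean of at least 5 CPM (0.418, median -0.178), and that of the nervous system list without control replicate 2 or AKH replicate 2 or 3 (0.153, 0.0908 and 0.187).

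**Figure D4:**
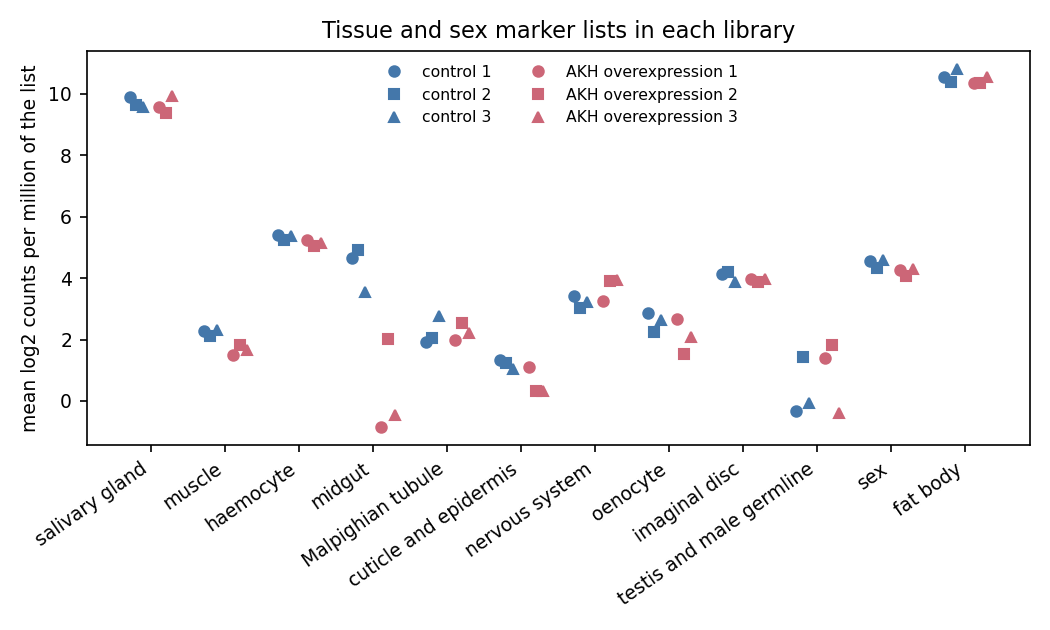
Mean log2 CPM of each tissue or sex marker list in each library, with control libraries in blue and AKH overexpression libraries in red and symbols for replicate 1 (circle), 2 (square) and 3 (triangle). Midgut markers lie between 3.54 and 4.92 in the controls and at -0.848, 2.00 and -0.453 in AKH replicates 1 to 3, and testis markers at 1.42, 1.41 and 1.81 in control replicate 2 and AKH replicates 1 and 2.

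The remaining marker lists had camera adjusted p above the threshold with all 6 libraries. Of 18 fat body markers 2 fell (Lsd-1 and Tsf1), also 2 when adjusted over the list alone (camera adjusted p = 0.697). Of 14 haemocyte markers 1 fell, NimC1, a phagocytosis receptor gene (-2.48, SE 0.31), also 1 when adjusted over the list alone (camera adjusted p = 0.858). In the imaginal disc list 1 of 15 genes fell, Obp99a (542 ± 81.4 to 154 ± 39.6 CPM). When adjusted over that list alone 1 had risen and 3 fallen (camera adjusted p = 0.620). Obp99a lay well above the mean of its list in every library, and the tissue its transcripts came from was not tested. The Malpighian tubule list had 1 risen gene of 14, Picot (1.34, SE 0.22), also 1 when adjusted over the list alone (camera adjusted p = 0.697). The edgeR test called 0 of 10 salivary gland, 10 oenocyte, 17 testis and male germline and 9 sex markers, with 0, 2, 2 and 4 at an unadjusted p under 0.05, 0, 0, 0 and 1 called by DESeq2 and 0 in each by limma-voom. When adjusted over the list alone these counts were 0, 0, 0 and 1, and their camera adjusted p were 0.957, 0.329, 0.109 and 0.739. Their most abundant members in control and AKH overexpression libraries were Sgs3 (10783 ± 1013 and 8347 ± 2381 CPM), svp (99.1 ± 12.2 and 78.7 ± 3.996), betaTub85D (5.62 ± 6.24 and 7.61 ± 6.08) and Yp3 (470 ± 212 and 166 ± 100.4). The testis list, with a median of 0.43, was called by camera as higher without control replicate 2 (adjusted p = 0.0013, median 1.59), without AKH replicate 3 (4.0e-06, 0.94) and with the replicate block (0.0238, 0.49), and not without any 1 of the other libraries (up to 0.563). Without control replicate 3 camera also called the glutathione transferase (0.0189), Malpighian tubule (0.0499) and imaginal disc (0.0499) lists, without AKH replicate 2 the glutathione transferase list (0.0399), and without AKH replicate 3 the humoral immunity list (0.0321). The calls of NimC1, Obp99a and Picot were lost in 2 (without control replicate 1 or AKH replicate 3), 1 (without AKH replicate 1) and 4 (without any 1 control or AKH replicate 3) of the 6 fits without 1 library, with adjusted p up to 0.0537, 0.0596 and 0.0824.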

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

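The fits without a pair of libraries were chosen after seeing the data; the other alternatives were fixed before the data were examined. The count of 404 changed genes stayed within 1.5 times under each other scaling, limma-voom, robust estimation, both filters and the RPKM tables (348 to 524 genes). DESeq2 called 986 genes, including all 404, with 40.1% of them higher. The cause was not tested. In simulated counts DESeq2 called more unchanged genes than edgeR and also recovered more of the changed ones. Stricter thresholds left by construction 132 genes at an adjusted p under 0.01 and 247 at a 2-fold change or more. With 1 library left out the count ranged from 144 to 479 and the share higher from 39.2% to 61.2%, where fewer samples enter each fit. Without control replicate 2 and AKH replicate 3, the ends of the first principal component, 872 genes were called, 73.5% of them higher, and 279 of the 404 remained. Without control replicate 2 and AKH replicate 2, with high testis or midgut markers, 227 were called, 44.1% of them higher, and 164 of the 404 remained; the cause of these shifts was not tested. No gene called in both fits changed direction under any alternative.

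Of 38 gene lists 11 were called by camera, 9 to 13 with RLE factors, with library size only, with a mean of at least 5 CPM, with the replicate block and with libraries left out, 0 with an estimated correlation and 1 with fry (genotype markers). Of the 11, the estimate was above the preset 0.01 in 10 and at -0.105 in genotype markers, so a larger correlation does not account for every loss. In those 10 lists fry gave adjusted p from 0.0583 (muscle markers) to 0.473 (nervous system markers). A call lost with an estimated correlation therefore does not show that a list was unchanged. Of the 70 called named genes, 36 kept their call when any 1 library was left out, 34 lost it at least once and 0 reversed. The uncalled betaTub85D, 0.43 on the log2 scale, was at -0.217 without AKH replicate 2 (adjusted p = 0.986) and at 2.40 without control replicate 2 and AKH replicate 3 (adjusted p = 0.0242); the cause was not tested. The log2 fold change of Akh stayed past the threshold under each alternative.

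The replicate numbers share no stated day or pool. Correlations of deviations from the group means between libraries of the same number were -0.369, 0.6004 and 0.502, and not every library correlated best with its own number. With the replicate block 430 genes were called, 304 of the 404 among them, which is a hint from the data and not the design. With 3 libraries per group, edgeR recovered 53% of simulated changes of 1 on the log2 scale, so an uncalled gene is not shown to be unchanged.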

Other observations

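The genes in this paragraph and the next were chosen after their values were seen, and their values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The mitochondrial aspartate-glutamate carrier aralar1 rose from 123 ± 13.6 to 519 ± 43.4 CPM (log2 fold change 2.08, SE 0.12, adjusted p = 0.0012), and the glutamate synthase gene CG9674 from 107 ± 19.3 to 359 ± 31.5 CPM (1.74, SE 0.15). The glutamine synthetase gene Gs2 fell by 0.70 (SE 0.13) on the log2 scale, as did Gdh and gb (-1.71 and -0.77). The cytosolic malate dehydrogenase Mdh1 was at 887 ± 137 and 1344 ± 39.5 CPM without passing the test (adjusted p = 0.069). The glycerol kinase gene Gk2 fell from 71.1 ± 10.8 to 14.7 ± 2.73 CPM, the peroxisomal transporter gene Abcd3 from 178 ± 36.7 to 50.2 ± 6.61 CPM, and the iron regulatory protein gene Irp-1B from 664 ± 124 to 78.1 ± 10.8 CPM. The calls of aralar1, CG9674, Gk2, Abcd3 and Irp-1B held when any 1 library was left out. That of Gs2 was lost in 5 of the 6 such fits, all except that without control replicate 3, with adjusted p up to 0.113.

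Of the circadian clock genes examined, 3 changed. The repressor gene tim fell from 9.37 ± 2.70 to 1.04 ± 0.0948 CPM (log2 fold change -3.16, SE 0.24, adjusted p = 0.0020), Cipc rose by 1.67 (SE 0.11) and cwo by 0.86 (SE 0.13). The values of per, vri, Pdp1, cry, cyc and Clk were -0.74, 0.26, -0.19, -0.07, 0.14 and 0.71 on the log2 scale, none past the test. Of these, per and Clk were scarce, with means of 0.566 and 0.480 CPM. No list of clock genes was fixed or tested. The calls of tim and Cipc held when any 1 library was left out, and that of cwo was lost in all such fits except that without control replicate 3, with adjusted p up to 0.125. The receptor gene mthl8 had 592 counts in the controls and 0 with AKH overexpression, at least 206-fold lower against a floor of 3 counts over the group.

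The tests below of the count of genes over other splits, of Hsp70Bb and of neighbouring genes were chosen after the result was seen. That of the count of lists over other splits was set before. The test of midgut RNA was set before it was run, but after midgut transcripts had been seen in AKH replicate 2. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 404 genes and the highest other split 743, so that 2 of the 10 splits, the real one included, gave as many genes; the remaining 8 called 0 each by edgeR, the tool used for the splits. For gene lists called by camera, 6 of the 10 splits gave as many as the real 11, and the highest other gave 16.

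The split with 743 calls sets control replicate 2 and AKH replicates 1 and 2 against the other 3 libraries, and points to a structure of the samples that crosses the groups. Of its calls 0 were among the 404 genes called between the groups. A gene that separates the groups varies within each side of this split, so little overlap was possible. The lack of overlap therefore does not show that the 404 genes are free of this structure. The mean log2 CPM of the testis and male germline markers was 1.42, 1.41 and 1.81 in those libraries and -0.312, -0.0730 and -0.407 in control replicates 1 and 3 and AKH replicate 3. No explanation was tested, since no label separates these libraries.

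The rise of Hsp70Bb to 380 CPM stands alone in its family. A heat shock response is argued against, since edgeR called 0 of the 13 other tested heat shock genes as risen, DESeq2 and limma-voom 0, the 4 at an unadjusted p under 0.05 were all lower, and the median log2 fold change of the 13 was -0.187. The 5 other listed Hsp70 copies together had 93 counts in the controls and 26 with AKH overexpression. Reads from Hsp70 sequence carried by the transgene cannot be told apart from an effect of the hormone on this gene. The log2 ratio of Akh to Hsp70Bb varied by 0.363 among the 3 AKH overexpression libraries, under the limit of 1 used for this test. That limit separates little, since 189 of the 198 other risen genes also met it. How many of them stayed within 0.363 was not counted, so whether Hsp70Bb follows Akh unusually closely is not known. The vector is not given in the sources used here.

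The 10 largest decreases among genes of at least 5 CPM, CG14273 to TotC, left little RNA in any AKH overexpression library. Midgut RNA missing from these libraries cannot be told apart from an effect of the genotype. In AKH replicate 2, where Jon65Aiv held 27.0% of its control mean, the median of the 10 was 1.58%, and 12 of the 15 midgut markers lay above that, with a median of 21.8%. These values go against midgut RNA but exclude nothing. They come from 1 library, and 3 midgut markers lay lower there, LManV at 0.695% and Jon99Cii and Jon44E at 0%. The test was set before it was run, but after midgut transcripts had been seen in this library. A difference between the parental lines in a chromosome segment may also lower such genes. Of the 9 that could be placed, 2 had an adjacent tested gene called in the same direction, while 204 of all 10705 tested genes fell. That is above the rate over all genes, but 2 genes are too few to decide, and neighbours can be related genes. The hormone's own effect stays open.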
